A study of Sus scrofa with 6 samples.

How the data were processed

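Gene expression was measured in 6 libraries of longissimus dorsi muscle, 3 from Wannanhua and 3 from Yorkshire pigs, all labelled as 5 months of age. The design text of the series instead speaks of piglets, and the age of the sample labels is the one given here. Per the labels' protocols, total RNA was purified, poly-A RNA was selected and fragmented, and paired-end libraries were made with random primers by a kit that does not mark strand. Reads from a gene and an antisense partner could therefore not be told apart. Ribosomal RNA and RNA without a poly-A tail are depleted by this selection, so small RNAs such as SNORD97 were outside the intended measurement. The submitters' processing notes name CASAVA 1.7, TopHat2 2.0.6 and the pig build Sscrofa10.2, with no role for any of them. The read counter, the gene annotation and any treatment of reads that match several places are not given in the sources used here.

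The table the authors deposited holds 17627 genes by Ensembl gene identifier, with an FPKM value and a value headed as a count for each library. FPKM, per the file headers, is fragments per kilobase of transcript, scaled by the library's mapped fragments. The authors' deposited count values were not whole numbers and are treated here as a signal, reads divided by a library factor. In each library between 99.71% and 99.82% of the values above 0 were whole multiples of a single step, within 0.01 of a read or, for large values, within a relative 1e-05. The step was sought around the most frequent value near 1, since 1 to 3 values per library lay below the value of 1 read and would mislead a search from the smallest value. A separate search from the smallest value found this step in Yorkshire 1 but not in the other 5 libraries, so the reads recovered there rest on the first search alone. Dividing by the step recovered between 16385602 and 21056699 reads per library. Gene symbols came from a table of Ensembl identifiers of unstated release, which matched 10384 of the 17627 identifiers (58.9%). The other genes were counted but not named, and no annotation of build Sscrofa10.2 was used here.

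Samples were grouped by the breed label. Each fold change is Wannanhua minus Yorkshire on the log2(FPKM + 1) scale, which understates the change of genes with low values. The main test was limma 3.58.1 in R 4.3.3, a linear model with breed as its only term and empirical Bayes moderation with trend and robust settings. Genes were kept at an FPKM of at least 1 in 3 or more libraries, which left 11798, or 11791 after 7 genes were removed as told below, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The design written beforehand asked for a count test if the table held whole counts, and for this limma fit otherwise; the limma fit applied because the deposited values were FPKM and scaled counts. For the same reason DESeq2 and its size factors were not run. A quasi-likelihood test in edgeR 4.0.16 on the recovered reads, with TMM scaling, was added after seeing the data and is an alternative only.

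A zero in this table can be a failed estimate. There were 7 genes that reached a scaled count of 10000 in some library and were listed at 0 in another: ACTA1, COX1, ATP8, ATP6, COX3 and the genes listed as MYH6 and MYH8. Of these 7, 5 were at 0 in Wannanhua 1, 5 in Wannanhua 2 and 2 in Yorkshire 2. They were left out of the test, a departure from the stated filter that was decided after seeing the data, and 342 genes passed the threshold with them kept. A zero of any other gene is reported only as listed at 0. Myosin heavy chain genes are similar in sequence, and how reads were shared among them is not given in the sources used here.

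Gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for naming genes, apart from those said to be added. The 37 lists covered fibre types, energy metabolism, fat, growth, matrix, immunity, stress and markers of other cell types. The 30 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 30. The alternatives were camera with an estimated correlation, fry with its directional p, the fit without a filter, quantile normalization, the replicate number as a block and each library left out. Of every list the count of members past the threshold is given over all genes and, where it differs, adjusted over the list alone.

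Named genes were chosen by rule. They are the 10 higher and 10 lower genes with the largest log2 fold change among genes past the threshold with a symbol, a mean of at least 1 FPKM and no overlap between breeds. To these were added up to 4 members of each list with the smallest adjusted p among those past the threshold, and a fixed set of muscle and fat genes whatever their p. The alternatives for the genes were limma without trend and robust settings, quantile normalization, no filter, a filter at 5 FPKM, a pseudocount of 0.1, each library left out and the replicate number as a block. Added after seeing the data were the count test, the 7 genes listed at 0 kept, and a minimum mean of 10 recovered reads in some breed.

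The tests were checked on simulated reads for the same genes, with the means, library sizes and dispersions of these libraries, in 5 runs of 100 genes per fold. The changed genes were drawn from those with a mean of at least 20 reads. For the comparison of Wannanhua with Yorkshire, limma on a mean of 11796 genes recovered 82.8% of genes changed 4-fold and 7.6% of those changed 2-fold. Of its calls 10.5% were unchanged genes, above the nominal rate. The count test, on a mean of 13074 genes, recovered 90.8% and 12.8%, with 9.0% of calls on unchanged genes. In 5 simulated runs camera found the list of 20 genes shifted 2-fold in all 5, and called 0 of 150 unchanged lists; genes were drawn independently there, which real genes are not. Intervals on read ratios are exact 95% binomial intervals and cover counting error only.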

Results

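Transcripts of longissimus dorsi, the long muscle of the back, were sequenced in 3 libraries from Wannanhua pigs, a local Chinese breed, and 3 from Yorkshire pigs, a lean commercial breed. Each library of a breed carries its own replicate number, but the labels do not state that they came from separate animals. The p-values therefore measure the spread between these libraries, which may in part be technical. Recovered reads numbered 16723877, 16385602 and 17940074 in Wannanhua 1, 2 and 3, and 17623977, 18049423 and 21056699 in Yorkshire 1, 2 and 3. Between 10726 and 11979 genes per library reached 1 FPKM, and the 10 most abundant genes took 19.0% to 26.5% of the reads. The lowest shares, 19.0% and 19.5%, were those of Wannanhua 2 and Yorkshire 2, where 5 and 2 abundant genes were listed at 0. Wannanhua 1, with 5 such genes, stood at 22.3%.

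The libraries separated by breed on the first principal component, which held 45.7% of the variance. The Wannanhua libraries scored from -45.08 to -16.56 on it and the Yorkshire libraries from 23.61 to 42.47. Wannanhua 3 was the Wannanhua library nearest to Yorkshire. The second component, with 23.1% of the variance, set Yorkshire 1 apart, at 41.64 against -30.32 and -17.27 in the other Yorkshire libraries. Spearman correlations across genes ran from 0.937 to 0.956 within Wannanhua, from 0.913 to 0.961 within Yorkshire and from 0.880 to 0.928 between breeds. All pairs of libraries within a breed differed by more than sampling noise, with a chi-square of their reads per degree of freedom of 37.2 or more.

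The series asks which genes differ in expression between the muscles of the 2 breeds. Genes of fatty acid oxidation were higher as a group in Wannanhua muscle, with 7 of 24 past the threshold, and genes of glycolysis were lower, with 6 of 22 past it, 5 lower and 1 higher. Both group calls were lost, each at an adjusted p = 0.80 with an estimated correlation. CPT1B (ENSSSCG00000022364), the muscle carnitine palmitoyltransferase that admits fatty acids to mitochondria, stood at 125 ± 42.7 FPKM in Wannanhua and 26.8 ± 3.32 in Yorkshire (SD, n = 3). Its log2 fold change was 2.12 ± 0.29 (SE; limma adjusted p = 0.0235). PKM (ENSSSCG00000001930), the muscle pyruvate kinase that ends glycolysis, stood at 859 ± 614 FPKM in Wannanhua and 4060 ± 595 in Yorkshire (SD, n = 3). Its log2 fold change was -2.45 ± 0.45 (SE; limma adjusted p = 0.0412).

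Of 11791 genes tested, 360 passed the threshold, 208 higher and 152 lower in Wannanhua. Of these, 124 higher and 89 lower genes had a symbol. The median size of the called log2 fold changes was 1.40, and 301 were at least 1 in size. Without adjustment 2605 genes had a p under 0.05. In 29.9% of the tested genes the breeds' libraries did not overlap, against 10% for a single gene whose libraries fall in random order. Genes vary together, so the share in any 1 split can lie far from 10%, and it was not computed for other splits. The median of all tested genes lay at 0.12, and at 0.00 after quantile normalization, which called 338 genes, 138 higher and 200 lower. Higher genes thus made up 57.8% of the calls as deposited and 40.8% after quantile normalization. The edgeR test on recovered reads called 400 of 13066 genes, 196 higher and 204 lower. It shared 271 genes with limma, all in the same direction. The count of 360 fell to 36 without Wannanhua 1, 19 without Wannanhua 2, 149 without Yorkshire 1, 46 without Yorkshire 2 and 11 without Yorkshire 3. Among the 360 were 11 genes that averaged under 10 reads per library in both breeds.

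Fatty acid oxidation genes were higher as a group by camera (adjusted p = 4.3e-08 with the preset correlation), a call lost at an adjusted p = 0.80 with an estimated correlation. All 24 tested members had a positive log2 fold change, with a median of 1.12, and 7 passed the threshold, all higher in Wannanhua (14 adjusted over the list alone, all higher). ACADM (ENSSSCG00000003776), the medium-chain acyl-CoA dehydrogenase, stood at 640 ± 75.6 FPKM in Wannanhua and 174 ± 14.4 in Yorkshire (SD, n = 3; log2 fold change 1.87 ± 0.18 SE, limma adjusted p = 0.00728). HADHA, the alpha subunit of the mitochondrial trifunctional protein, was 3.04-fold higher by group means (270 ± 47.0 against 88.8 ± 6.59 FPKM; limma adjusted p = 0.0159). ETFDH, which passes electrons from acyl-CoA dehydrogenases to ubiquinone, was 2.99-fold higher (216 ± 45.6 against 72.2 ± 14.7 FPKM; limma adjusted p = 0.0312). The other 3 called members were PDK4, SLC25A20 and ACADL, chosen for mention after their values were seen except PDK4. PDK4 (ENSSSCG00000015334), the kinase that shuts down pyruvate dehydrogenase, stood at 664, 778 and 999 FPKM in Wannanhua 1, 2 and 3. In Yorkshire 1, 2 and 3 it stood at 26.1, 226 and 29.0 FPKM (log2 fold change 3.82 ± 0.76 SE, limma adjusted p = 0.0465). PDK4 did not pass in the count test (adjusted p = 0.0777; 0.00176 to 0.158 over its 15 alternatives), nor did ACADL or SLC25A20 (adjusted p = 0.0634 and 0.0925), so 4 of the 7 passed there.

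Glycolysis and glycogen genes were lower as a group, with a median log2 fold change of -1.35 over 22 tested members, 19 of them negative. Camera gave an adjusted p of 8.3e-09, and an adjusted p = 0.80 with an estimated correlation. Of the 22, 5 were lower and 1 higher past the threshold (14 lower and 2 higher adjusted over the list alone). TPI1, triosephosphate isomerase, stood at 1214 ± 411 FPKM in Wannanhua and 3526 ± 96.6 in Yorkshire (SD, n = 3; log2 fold change -1.59 ± 0.27 SE, limma adjusted p = 0.0366). GPI, which interconverts glucose and fructose phosphates, was lower by 3.95-fold (368 ± 211 against 1454 ± 165 FPKM; limma adjusted p = 0.0397). PKM was higher in Wannanhua 3, at 1566 FPKM, than in Wannanhua 1 and 2, at 539 and 471, and the lowest Yorkshire library stood at 3704. LDHA and ENO3, also lower, are named after their values were seen (limma adjusted p = 0.0495 for both); neither passed in the count test (adjusted p = 0.0535 and 0.0621). The member higher past the threshold, GBE1, makes the branches of glycogen and is no step of glycolysis (37.1 ± 14.9 against 9.87 ± 2.48 FPKM, limma adjusted p = 0.0412). HK2, a hexokinase of glycolysis named after its values were seen, was the other member higher over the list alone. It stood at 17.6 ± 7.37 FPKM in Wannanhua and 7.30 ± 0.50 in Yorkshire (limma adjusted p = 0.0143 over the list alone, 0.101 over all genes).

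Genes of slow-twitch fibres were higher as a group, with a median log2 fold change of 1.45 over 7 members, all positive. Camera gave an adjusted p of 0.00229, and an adjusted p = 0.80 with an estimated correlation. The mean log2 level of the list was 11.09 and 11.22 in Wannanhua 1 and 2, but 9.48 in Wannanhua 3, close to 9.43 in Yorkshire 1. CSRP3 and ANKRD2, which are stretch-responsive muscle proteins, passed the threshold (2 adjusted over the list alone). CSRP3 stood at 1708 ± 890 FPKM in Wannanhua and 135 ± 119 in Yorkshire (SD, n = 3; log2 fold change 3.81 ± 0.67 SE, limma adjusted p = 0.0397). ANKRD2 stood at 446 ± 140 and 64.0 ± 18.2 FPKM (log2 fold change 2.77 ± 0.32 SE, limma adjusted p = 0.0115). The contractile members did not pass; TNNI1, slow troponin I, named after its values were seen, stood at 5496 ± 3310 and 1733 ± 738 FPKM (limma adjusted p = 0.196, and 0.0305 without Wannanhua 3).

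Genes of fast-twitch fibres were lower as a group, with a median of -1.48 over 8 members, all negative. Camera gave the list an adjusted p of 1.5e-06, and an adjusted p = 0.80 with an estimated correlation. The mean log2 level of the fast-twitch list was 10.03 and 9.90 in Wannanhua 1 and 2, but 11.43 in Wannanhua 3, against 11.89 to 12.06 in Yorkshire. CASQ1, the calcium store protein of the sarcoplasmic reticulum, was the member past the threshold (5 adjusted over the list alone), at 1552 ± 310 FPKM in Wannanhua and 3646 ± 447 in Yorkshire (SD, n = 3; limma adjusted p = 0.0435). The count test gave CASQ1 an adjusted p of 0.0611. The calcium handling and excitation list, which shares CASQ1 with it, had a median of -0.38 over 16 members, 13 of them negative (1 lower past the threshold, 2 adjusted over the list alone; camera adjusted p = 0.00119). It too was lost with an adjusted p = 0.80 with an estimated correlation, and its median was -0.21 without Yorkshire 2. MYH7, MYH1, MYH2 and MYH4, the myosin heavy chains that name the fibre types, have no tested value here.

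**Figure D1:**
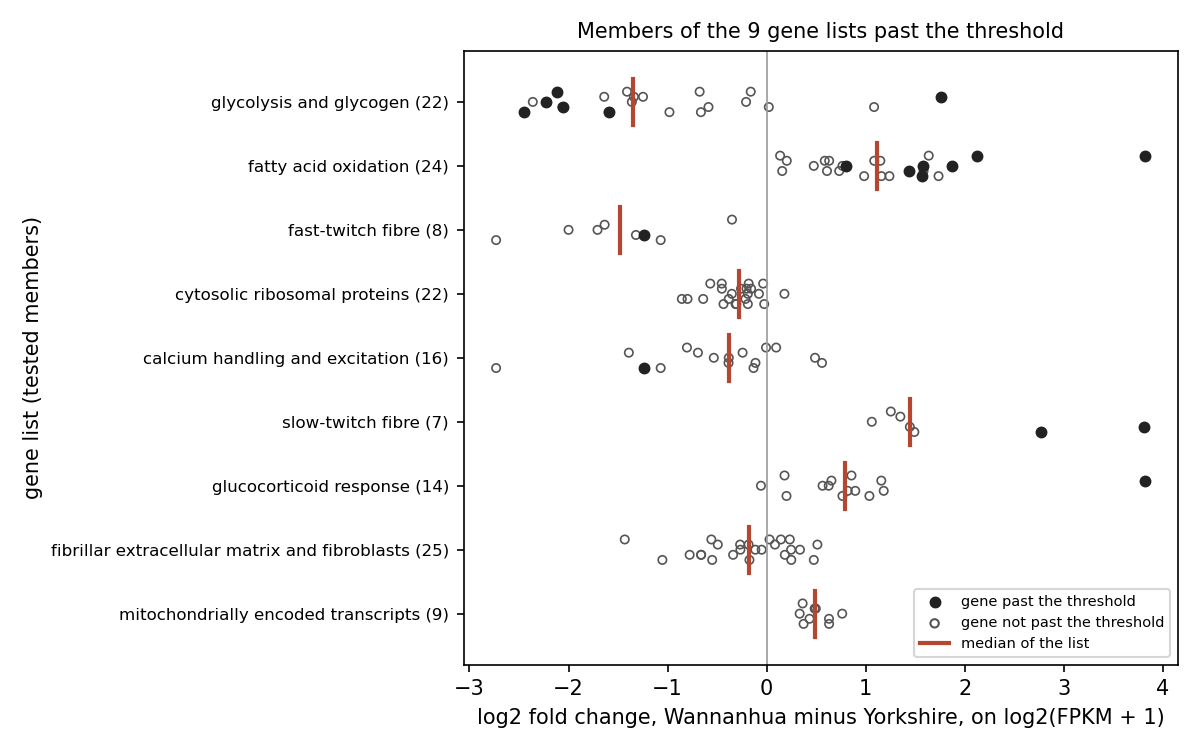
Log2 fold change of each tested member (horizontal axis, Wannanhua minus Yorkshire, on log2(FPKM + 1)) in the 9 gene lists past the camera threshold with the preset correlation (vertical axis, number of tested members in brackets). Filled points passed the threshold as genes, open points did not, and bars mark list medians; the 24 fatty acid oxidation genes all lie above 0 and the 8 fast-twitch genes all below.

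**Figure D2:**
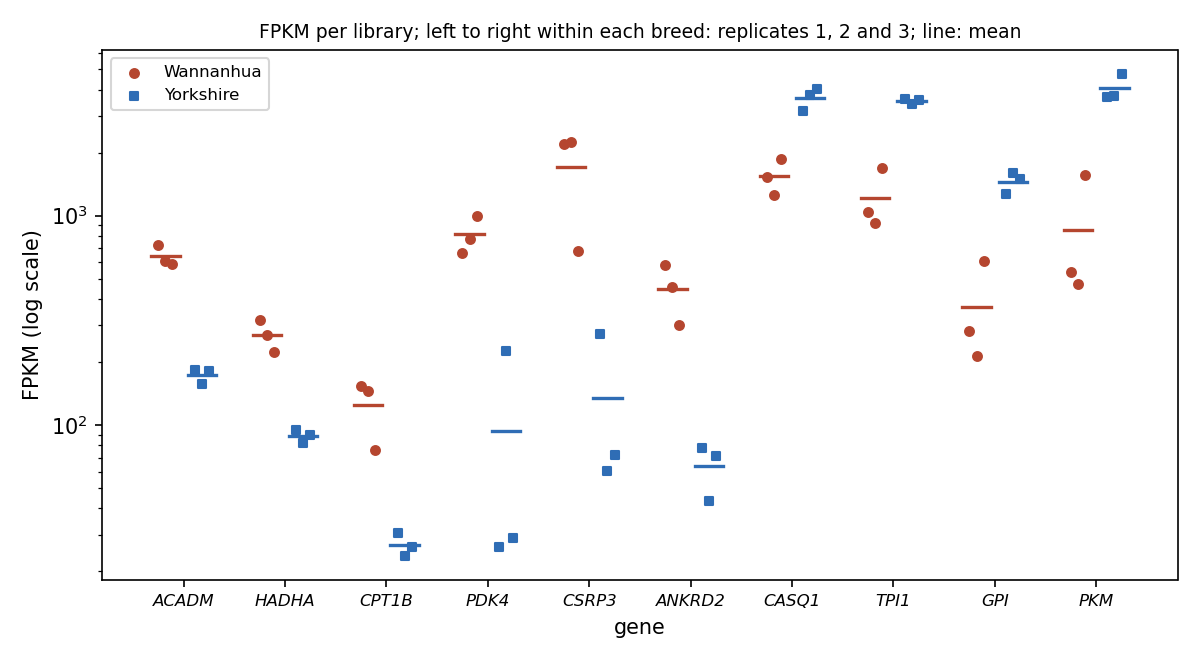
FPKM on a log scale (vertical axis) of 10 named genes (horizontal axis) in each of the 3 Wannanhua (circles) and 3 Yorkshire (squares) libraries, with lines at breed means. ACADM, HADHA, CPT1B, PDK4, CSRP3 and ANKRD2 lie above and CASQ1, TPI1, GPI and PKM below Yorkshire in every Wannanhua library.

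Cytosolic ribosomal protein genes had a median of -0.28 over 22 members, 21 of them negative, and 0 passed in limma, over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05, 0 in edgeR). The camera adjusted p was 4.1e-06, and an adjusted p = 0.80 with an estimated correlation. The median was -0.15 without Yorkshire 1. The glucocorticoid response list had a median of 0.79 over 14 members, of which PDK4 passed (2 adjusted over the list alone; camera adjusted p = 0.0150, and an adjusted p = 0.80 with an estimated correlation). Without Wannanhua 3 its median was 0.52 and its adjusted p 0.0718. The 9 tested mitochondrially encoded transcripts, all positive with a median of 0.48, had 0 members past limma's threshold either way (2 at an unadjusted p under 0.05, 0 in edgeR; camera adjusted p = 0.0477, and an adjusted p = 0.92 with an estimated correlation). Their adjusted p was 0.30 without Wannanhua 1 and 0.50 without Yorkshire 2, with medians of 0.29 and 0.23. The matrix and fibroblast list had a median of -0.17 over 25 members, with 0 past limma's threshold either way (3 at an unadjusted p under 0.05, 0 in edgeR; camera adjusted p = 0.0466, and an adjusted p = 0.92 with an estimated correlation). It was lost without Wannanhua 2, Wannanhua 3 or Yorkshire 2 (adjusted p = 0.057, 0.14 and 0.81) and after quantile normalization (0.065). Its median turned to 0.14 without Yorkshire 2, and was -0.45 without Yorkshire 1 and -0.30 after quantile normalization. Thus 9 of 30 lists passed with the preset correlation, 4 higher and 5 lower, and 0 with an estimated correlation or with fry's directional p. By fry's mixed p, which tests change in either direction, 16 passed. At an unadjusted p under 0.05 stood 0 lists with an estimated correlation and 5 by fry's directional p.

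The remaining 21 lists did not pass camera as reported. Among fat genes, the lipid droplet and lipolysis list had a median of 0.74 over 8 members (camera adjusted p = 0.0954), with 0 past limma's threshold, 2 adjusted over the list alone, 4 at an unadjusted p under 0.05 and 0 in edgeR. It passed without Wannanhua 1, without Yorkshire 1 and after quantile normalization (adjusted p = 0.0483, 0.0447 and 0.0316). The triglyceride synthesis list had a median of 0.20 over 14 members (0.387), of which 1 passed, GPAM, the first enzyme of glycerolipid synthesis. GPAM stood at 27.7 ± 16.2 FPKM in Wannanhua and 3.22 ± 0.63 in Yorkshire (SD, n = 3; limma adjusted p = 0.0422). The adipocyte list had a median of 0.40 over 12 members (0.530), of which 1 passed, GPD1, and 3 adjusted over the list alone, 2 higher and 1 lower. Its median was 0.11 without Yorkshire 1, and 0.73 and 0.74 without Yorkshire 2 and 3. GPD1, a cytosolic glycerol-3-phosphate dehydrogenase also active in muscle, was lower (376 ± 91.8 against 1389 ± 251 FPKM; limma adjusted p = 0.0223). Cholesterol synthesis had a median of -0.13 over 16 members (0.0954), with 0 past limma's threshold, 1 adjusted over the list alone, 5 at an unadjusted p under 0.05 and 0 in edgeR. It passed without Yorkshire 1 and after quantile normalization (adjusted p = 0.010 and 0.0316).

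Muscle proteolysis had a median of 0.17 over 18 members (camera adjusted p = 0.530), of which 2 passed, both higher. FBXO32, the muscle ubiquitin ligase atrogin-1, stood at 169 ± 68.0 FPKM in Wannanhua and 29.3 ± 8.17 in Yorkshire (SD, n = 3; limma adjusted p = 0.0295). GABARAPL1, an autophagosome protein, stood at 47.1 ± 19.8 and 16.2 ± 1.74 FPKM (limma adjusted p = 0.0498). Heat shock genes had a median of 0.04 over 18 members (0.927), of which 1 passed, the small heat shock protein HSPB6 (442 ± 239 against 73.8 ± 19.9 FPKM; limma adjusted p = 0.0495; 4 adjusted over the list alone). Growth factor signalling had a median of -0.06 over 16 members (0.344), of which 1 passed, the insulin-like growth factor binding protein IGFBP7 (84.7 ± 20.3 against 175 ± 13.7 FPKM; limma adjusted p = 0.0465; 2 adjusted over the list alone). The interferon list had a median of -0.03 over 18 members (0.302), of which 1 passed, the antiviral enzyme OAS2 (2.07 ± 0.35 against 6.60 ± 2.24 FPKM; limma adjusted p = 0.0495); the list passed without Wannanhua 1 (adjusted p = 0.0281). The hypoxia list had a median of -0.03 over 13 members (0.518), of which 1 passed, ANKRD37 (1.57 ± 0.67 against 4.89 ± 0.71 FPKM; limma adjusted p = 0.0434; 2 adjusted over the list alone).

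No member passed, over all genes or adjusted over the list alone, in the lists that follow, whose medians stand with camera's adjusted p in brackets. Of their 170 members, 20 had an unadjusted limma p under 0.05, and edgeR called 2. For energy metabolism these were the tricarboxylic acid cycle at 0.21 (0.338), nuclear-encoded oxidative phosphorylation at 0.24 (0.402) and oxidative regulators at 0.19 (0.387). Oxidative phosphorylation passed without Wannanhua 3, without Yorkshire 1 and after quantile normalization (median 0.43, 0.51 and 0.29; adjusted p = 0.0270, 0.000285 and 0.0302), and its median was -0.01 without Yorkshire 2. The tricarboxylic acid cycle passed without Yorkshire 1 and after quantile normalization (median 0.37 and 0.20, adjusted p = 0.00791 and 0.0439), and its median was 0.06 without Yorkshire 2. For growth these were myogenic regulators at 0.00 (0.570) and myostatin signalling at 0.16 (0.693). Markers of other cells were the basement membrane at -0.10 (0.104), macrophages at -0.14 (0.387) and endothelium at 0.21 (0.965). The basement membrane list passed without Wannanhua 2 or Yorkshire 1 (adjusted p = 0.0111 and 0.00508). Immune lists were antigen presentation at -0.13 (0.230) and complement and coagulation at -0.02 (0.387). The circadian clock lay at 0.25 (0.923) and the immediate-early and slaughter stress genes at 0.21 (0.975). Camera ranked the myogenic, myostatin, endothelial and immediate-early lists as lower despite medians above 0. The mean of the myogenic list was -0.10, and the complement list had a mean of 0.04 against its median of -0.02. The tendon, lymphocyte, erythrocyte, nerve, cell cycle, Y-linked and X-inactivation lists had 3, 2, 1, 4, 2, 0 and 0 tested members and were not tested.

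Among the genes with the largest changes, AMPD3 (ENSSSCG00000022492), an AMP deaminase, stood at 29.6 ± 15.04 FPKM in Wannanhua and 1.44 ± 0.60 in Yorkshire (SD, n = 3; log2 fold change 3.54 ± 0.39 SE, limma adjusted p = 0.00950). SLC38A4, an amino acid transporter, stood at 24.3 ± 6.17 and 3.41 ± 1.14 FPKM (limma adjusted p = 0.00914). TECRL and ZNF385A were also higher, with log2 fold changes of 2.93 and 2.85 (limma adjusted p = 0.0440 and 0.0397). SNORA36B and SNORD97, small nucleolar RNAs, passed on 7 and 3 reads over the 3 Wannanhua libraries (limma adjusted p = 0.00123 and 3.55e-05). Both were listed at 0 in every Yorkshire library, and the count test did not include them.

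HOXC10 (ENSSSCG00000022728), a homeobox gene of the posterior body axis, showed the largest fall by the naming rule. It was listed at 0, 0 and 1.24 FPKM in Wannanhua 1, 2 and 3, and at 34.6, 68.1 and 54.0 FPKM in Yorkshire 1, 2 and 3 (log2 fold change -5.29 ± 0.38 SE, limma adjusted p = 0.00143). With the listed zeros taken as 0 reads, it had 13 reads over the Wannanhua and 1783 over the Yorkshire libraries. That is a 123-fold difference per recovered read (exact 95% binomial interval 72.0 to 232). HOXA9 (ENSSSCG00000028997), of the same family, had 4 and 213 reads on the same terms (limma adjusted p = 0.00143). SHISA2 (ENSSSCG00000030113), an inhibitor of Wnt and FGF receptor maturation, stood at 6.33 ± 4.54 FPKM in Wannanhua and 198 ± 24.9 in Yorkshire (SD, n = 3; log2 fold change -5.01 ± 0.51 SE, limma adjusted p = 0.00793). CARNS1, which makes carnosine, stood at 25.5 ± 13.4 and 172 ± 5.96 FPKM (limma adjusted p = 0.0174). SLC37A4, the glucose-6-phosphate transporter of the endoplasmic reticulum, stood at 23.6 ± 12.7 and 187 ± 9.11 FPKM (limma adjusted p = 0.00950). The remaining members of the 10, SLC7A8, SNTB1, NTMT2, ARG2 and SNCG, had log2 fold changes of -3.37, -3.31, -2.69, -2.65 and -2.60 (limma adjusted p = 0.0321, 0.0338, 0.0412, 0.0397 and 0.00143). Of the 36 named genes past the threshold, HOXC10, HOXA9, SNCG, SNORA36B and SNORD97 passed under every alternative in which they were tested. Only HOXC10 was tested in all 15. HOXA9 and SNCG were tested in 12, none of them with a Yorkshire library left out. SNORA36B and SNORD97 were tested in 10, without the count test, the minimum of 10 reads and the fits that left out a Wannanhua library.

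Several genes often studied in pig muscle did not pass. MSTN, the myostatin that limits muscle mass, stood at 5.31 ± 2.21 FPKM in Wannanhua and 14.9 ± 4.31 in Yorkshire (SD, n = 3; limma adjusted p = 0.0639). In the count test MSTN passed (adjusted p = 0.0346; 0.0304 to 0.207 over its 15 alternatives). MYOD1, a myogenic regulator, stood at 5.56 ± 5.15 and 15.8 ± 5.84 FPKM (limma adjusted p = 0.136). PRKAG3, a subunit of the AMP-activated kinase in which variants alter pig muscle glycogen, stood at 13.6 ± 7.25 and 34.6 ± 17.2 FPKM (0.149). IGF1 stood at 2.49 ± 0.86 and 3.47 ± 1.95 FPKM (0.662). The fat genes PLIN1, SCD and FASN had limma adjusted p values of 0.361, 0.773 and 0.807. In Yorkshire 1 they stood at 0.42, 0.90 and 0.89 FPKM, and between 5.44 and 9.95 FPKM in the other Yorkshire libraries. PPARGC1A, a regulator of mitochondrial genes, stood at 26.6 FPKM in Yorkshire 3 and at 6.81 FPKM or less in each other library (0.920). IGF2, ADIPOQ, LEP, FABP3, FABP4, LPL and MYOG have no tested value here.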

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

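Every alternative added after seeing the data is named in the account of processing; the others were planned. All genes called as reported kept their direction under every alternative in which they were tested, but the number of calls did not hold. The 360 genes became 69 without a filter on low values, where 17620 genes were tested, and 11 to 504 when 1 library was left out. Calls numbered 36 without Wannanhua 1, 19 without Wannanhua 2, 149 without Yorkshire 1, 46 without Yorkshire 2 and 11 without Yorkshire 3, where fewer samples enter the fit; without Wannanhua 3 they numbered 504. Between 285 and 424 genes passed under the other alternatives, namely limma without trend and robust settings, quantile normalization, a filter at 5 FPKM, a pseudocount of 0.1, the count test, the genes listed at 0 kept and a minimum of 10 reads. With the replicate number as a replicate block 205 genes passed, 178 of them among the 360; the cause was not tested. The numbers are not taken to pair the samples, since libraries of the same number deviated together with correlations of 0.10, -0.01 and 0.11, and Wannanhua 2 did not correlate best with its own number.

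Of the 36 named genes past the threshold, 34 could be tested with a library left out, but not the same 34 for each breed. SNORA36B and SNORD97 dropped out where a Wannanhua library was left out, HOXA9 and SNCG where a Yorkshire library was. Of the 34, 10, 5 and 29 passed without Wannanhua 1, 2 and 3, and 17, 10 and 3 without Yorkshire 1, 2 and 3. The 3 without Yorkshire 3 were HOXC10, SNORA36B and SNORD97. The count test kept 32 of 34. Of the 36, 15 passed without a filter, 28 with the replicate block, 29 with a pseudocount of 0.1 and 30 after quantile normalization. Of 522 values of these genes under alternatives, 178 missed the threshold and 0 changed direction. Of the genes named but not past the threshold as reported, MSTN passed under 3 alternatives, and TNNI1 and HOXD9 under 1 each, the fit without Wannanhua 3.

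The 9 lists became 0 with an estimated correlation, 0 with fry's directional p and 7 to 14 when 1 library was left out, the 14 without Yorkshire 1. They became 11 without a filter, 12 after quantile normalization, and 9 with the replicate block. At 16385602 to 21056699 reads per library and 3 libraries per breed, limma recovered 7.6% of genes changed 2-fold in simulation. There 100 genes were changed per fold, and the share with more genes changed was not simulated.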

Other observations

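The genes named in this part were chosen after their values were seen. Also chosen after the result was seen were the tests of the HOX spread within Wannanhua, of HOX paralogue number and of the fibre position of Wannanhua 3. MYBPC1, the slow isoform of myosin-binding protein C, was higher, at 2943 ± 1185 FPKM in Wannanhua and 591 ± 94.7 in Yorkshire (SD, n = 3; limma adjusted p = 0.0295). ACTN2, an alpha-actinin of the Z-disc, was higher too, at 2231 ± 777 and 528 ± 51.2 FPKM (limma adjusted p = 0.0312). AK1, an adenylate kinase, was lower, at 342 ± 221 against 1557 ± 165 FPKM (limma adjusted p = 0.0381). PFKL, the liver-type phosphofructokinase, was higher, at 15.8 ± 4.32 against 2.64 ± 0.36 FPKM (limma adjusted p = 0.00914), opposite to PKM and TPI1. All 4 passed in the count test, and their adjusted p reached 0.134, 0.131, 0.143 and 0.0690 under the least favourable alternative.

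TBX3, a T-box transcription factor, was higher, at 5.96 ± 1.85 FPKM in Wannanhua and 0.92 ± 0.17 in Yorkshire (SD, n = 3; limma adjusted p = 0.0183). PITX3, MEOX1 and ZIC4, homeobox and zinc-finger factors, were also higher, with log2 fold changes of 1.91, 1.87 and 1.29 (limma adjusted p = 0.0213, 0.0499 and 0.0321). PBX3, a partner of HOX proteins, was lower, at 1.29 ± 0.58 against 9.80 ± 2.13 FPKM (limma adjusted p = 0.00950). NRN1 and KIT were lower too, with log2 fold changes of -2.51 and -1.64 (limma adjusted p = 0.00728 and 0.0390). All 7 passed in the count test, and the highest adjusted p over the alternatives ran from 0.0521 for NRN1 to 0.172 for MEOX1.

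HOX genes mark position along the body axis. Of 16 that reached 1 FPKM in some library, 12 were tested between breeds and 3 passed, HOXC10, HOXA9 and HOXA10, all lower in Wannanhua. HOXA10 was listed at 0 in every Wannanhua library and had 97 reads over the Yorkshire libraries (limma adjusted p = 0.00123). HOXD9 stood at 0.20, 0.87 and 12.4 FPKM in Wannanhua 1, 2 and 3, and at 12.4 to 13.3 in Yorkshire. HOXC6 stood at 0.24 FPKM in Wannanhua 1 and at 13.01 to 19.8 in the other 5 libraries, and HOXA3 at 15.5 FPKM in Wannanhua 1 and at 0.76 to 2.50 in the others. Neither HOXD9, HOXC6 nor HOXA3 passed between breeds (limma adjusted p = 0.171, 0.601 and 0.761), though HOXD9 did without Wannanhua 3 (0.00380).

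Lower depth in Wannanhua is argued against, since 0.13% of 5264 tested genes at the Yorkshire level of the called HOX genes fell below 10% of their own Yorkshire mean in every Wannanhua library. Within Wannanhua the median SD of 16 HOX genes was 0.63 (log2), against a median of 0.24 over 10000 random lists matched on level (percentile 100). Within Yorkshire it lay at percentile 74.9. The percentiles restate what drew attention to these genes and are no independent support. Breed alone cannot make libraries of 1 breed differ, yet recovered reads in Wannanhua 1, 2 and 3 numbered 4, 331 and 300 for HOXC6. They numbered 419, 21 and 22 for HOXA3, and 5, 21 and 280 for HOXD9. That spread within 1 breed is not set by breed, which would hold of any gene that varied between these libraries. HOXC6, HOXA3 and HOXD9 were picked for this spread, so their reads cannot decide what set the difference between breeds. For HOXC10, HOXA9 and HOXA10, at 13 reads or fewer in each Wannanhua library, breed as the sole source stays open. A candidate explanation is that the muscle was taken at different levels of the body axis. The log2 fold change fell with paralogue number across the 16 genes (Spearman rho = -0.80, Pearson r = -0.77, permutation p = 0.00039). Over the 13 genes not called, 4 of them not tested, rho was -0.67. These 13 still hold the posterior genes HOXD9 and HOXD10, with log2 fold changes of -2.17 and -1.49. HOXD10, not tested, had 0 reads over the Wannanhua libraries, and 1, 93 and 43 in Yorkshire 1, 2 and 3. The trend without these posterior genes was not computed, and HOX genes of a cluster are not independent. The labels give no sampling level, and a breed difference in HOX expression and a difference between animals of a breed remain open and untested.

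For the glycolytic and fast-fibre genes lower, and fatty acid oxidation genes higher, in Wannanhua, scaling of the FPKM values is argued against, since after quantile normalization the median log2 fold changes stayed at -1.30 for glycolysis and 1.03 for fatty acid oxidation. The mean log2 level of slow minus fast fibre genes was 1.07 and 1.31 in Wannanhua 1 and 2, -1.95 in Wannanhua 3, and -2.51, -3.88 and -3.35 in Yorkshire 1, 2 and 3. The mean level of HOX genes of paralogue group 9 and above was 0.05, 0.27 and 1.01 in Wannanhua and 2.99, 3.66 and 3.39 in Yorkshire. The mean of the lower groups did not move the other way, at 1.3, 1.5 and 1.5 against 1.8, 1.7 and 1.7, but it pools genes of both directions. HOXA2, HOXA3, HOXB2, HOXB3 and HOXB4 had log2 fold changes of 0.20 to 0.75. HOXA5, HOXA7, HOXB7, HOXC6, HOXD1 and HOXD4 had -1.36 to -0.25, and none of these genes passed between breeds. A difference in sampling level, which no label gives, may contribute to the fibre and metabolic differences. It cannot be told apart from breed here, because the mean of HOX groups 9 and above lay lower in every Wannanhua than in every Yorkshire library.

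The 11 genes called on under 10 reads per library include features whose FPKM is large for their reads. ENSSSCG00000025162, without a symbol, had 3 reads in Wannanhua and 24 in Yorkshire, listed as means of 51279 and 378195 FPKM. Short features may turn a few reads into large FPKM values, and 1 of the 11, SNORD97, had an exact binomial p of 0.05 or more on its reads (two-sided, p = 0.106). That leaves the explanation open, since the exact 95% interval of that share runs from 0.23% to 41.3% and the genes were picked on the same reads.

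The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The breeds gave 360 genes and the highest of the other splits 4, and 1 of the 10 splits, the real one, gave as many genes. For the lists, 6 of the 10 splits gave as many as the 9 of the real split, with a highest of 12 in another.

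Among the 9 pairs made of 1 library of each breed, 1 pair, Wannanhua 1 and Yorkshire 1, had genes on in both and nearly off in the other 4 libraries. There were 4 such genes, at 100 or more scaled reads in both and at most 5% of that elsewhere, and none has a symbol. ENSSSCG00000012178 had 1995 and 2255 reads in the pair and at most 17 in the others, and ENSSSCG00000026430 had 2173 and 2379 against at most 22. The labels give no sex, and the Y-linked and X-inactivation lists had 0 tested members.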
